A study of Homo sapiens with 9 samples.

How the data were processed

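RNA from the Ewing sarcoma cell line A-673 was measured on 9 Clariom D Human arrays, 3 for cells given a non-targeting control pool of small interfering RNAs (siRNAs), 3 for cells given a pool against E2F2 and 3 for cells given a pool against GATA2. Per the labels' protocols, the pools were used at 30 nM, the transfection was repeated after 48 h and RNA was taken 96 h after the first transfection. The labelling was with biotin, so each array has 1 colour. Samples were assigned to groups and replicate numbers from their titles.

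The deposited values are log2 signals per transcript cluster, a set of probes that the manufacturer assigns to a gene or transcript. Per the series' design text, the authors computed them by SST-RMA in Transcriptome Analysis Console 4.0, using version 2 of the array description file, and the submitters' processing notes name the same tool and RMA. This algorithm corrects background and normalizes the arrays together, so a change shared by nearly all genes would not be visible. The log2 scale was read from the values, which run from 1.66 to 19.93 with array medians between 4.30 and 4.36. The highest values sit at a common ceiling of 19.93, so changes of the brightest clusters can be understated. No detection calls were used, and the scanner files were not used here. The genome build is not given in the sources used here, so no coordinates are printed. For arrays, precision is limited by their number, 3 per group.

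Of the 135750 transcript clusters, 36176 had exactly 1 gene symbol in the platform table, 1119 had several and 98455 had none there. Clusters with several symbols were not named. An Entrez gene identifier matched the RefSeq gene table for 25516 of the clusters with 1 symbol, and 0 symbols needed updating. These clusters stood for 33616 genes, of which 1576 had more than 1 cluster. For such a gene the cluster with the highest mean over the 9 arrays was used. Genes whose mean over the 9 arrays lay above 4.31, the median of all cluster means, were tested, which left 22225 genes, 13640 of them protein-coding.

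All tests used limma 3.58.1 in R 4.3.3 on the log2 values as deposited. A linear model with 1 mean per group was fitted to the 9 arrays (lmFit, eBayes), with 6 residual degrees of freedom, and 3 contrasts were taken: E2F2 knockdown against control, GATA2 knockdown against control, and E2F2 knockdown against GATA2 knockdown. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, and genes with an adjusted p under 0.05 are said to have risen, fallen or changed. The targeted genes were read before the filter on dim clusters. Errors are the SD over the 3 arrays of a group or the standard error (SE) of the fitted log2 change.

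Gene lists, the rule for naming genes, the comparisons with their tests and all alternatives but 1 were chosen before the data were examined. Some tests of explanations were chosen later and are named where they are given. The 25 lists hold 1043 genes, of which 854 were tested, and cover DNA replication, mitosis, the E2F and RB family, GATA-linked hematopoietic and endothelial genes, genes activated or repressed by EWSR1-FLI1 (the fusion oncoprotein of this tumour), extracellular matrix, neural genes, p53 targets, apoptosis, interferon response, NF-kB and inflammation, hypoxia and glycolysis, unfolded protein and integrated stress, cholesterol and lipid synthesis, MYC and ribosome biogenesis, ribosomal proteins, the respiratory chain, autophagy and lysosome, immediate early and AP-1 genes, histones, the siRNA machinery, and markers of fibroblasts, epithelial cells and hematopoietic cells. They were compiled from general knowledge and not from these samples. Each was tested with camera at a preset correlation of 0.01, adjusted over the 25 lists, with an estimated correlation and fry as alternatives. The camera test compares a list with the other genes, whereas fry tests it against no change, so the 2 can differ without conflict. The named genes are the target, the 12 protein-coding genes with the largest rise and the 12 with the largest fall in each knockdown whose arrays did not overlap those of the control, 5 each way in the direct comparison, the 4 that rose and the 4 that fell most in both knockdowns, up to 4 members that changed in each list (or, with none, the 2 with the smallest p), and the E2F and GATA families. Any other gene named is said to have been chosen after its values were seen.

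Chance levels for genes shared by both knockdowns came from 100 simulations of unchanged groups set against the same control arrays. The alternatives were quantile normalization, centring each array on its median, no filter on dim clusters, a filter at the 75th percentile, the mean of a gene's clusters, only the 6 arrays compared, an intensity trend with a robust prior, array weights, the replicate number as a block, a minimum absolute log2 change of 1, all clusters of the file, and leaving out each array in turn. Restriction to clusters with an Entrez identifier was added after seeing the data.

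The procedure was tested on simulated data, with 200 of the 22225 genes changed. For E2F2 knockdown against control it recovered 1.61% of genes changed by 0.5 on the log2 scale, 68.7% of those changed by 1 and 95.8% of those changed by 2, and 5.74% of its calls were unchanged genes. For GATA2 knockdown against control the shares were 6.90%, 51.5% and 93.4%, with 2.68% of calls false. For the direct comparison they were 6.45%, 60.8% and 92.2%, with 6.09% of calls false. Each share came from 1 draw per comparison, with genes drawn independently. In the real data 13.9%, 10.4% and 10.2% of the genes tested passed in these 3 comparisons, so the shares do not give the sensitivity there. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.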

Results

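The transcriptome of A-673, an established cell line of Ewing sarcoma (a bone and soft tissue tumour driven by the EWSR1-FLI1 fusion), was profiled after siRNA knockdown of the transcription factors E2F2 or GATA2. The series asks what these factors contribute to gene expression in this cell model. The 9 arrays fell into a control group, an E2F2 knockdown group and a GATA2 knockdown group, with 3 arrays each. Across the genes tested, arrays of the same group correlated at 0.992 to 0.994 and arrays of different groups at 0.983 to 0.988. The labels number the replicates but do not say that they came from separate cultures, so p-values measure only the spread between these arrays, which may be technical. Effects of the siRNA pools on transcripts other than their targets were not tested, so a change after a knockdown need not follow from the loss of its target.

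The targeted genes were examined first. The E2F2 transcript cluster (TC0100013287.hg.1) had a log2 signal of 7.79 ± 0.38 (SD, n = 3) in control cells, 5.64 ± 0.37 in E2F2 knockdown and 8.47 ± 0.23 in GATA2 knockdown. In the E2F2 knockdown arrays it read 5.59, 5.30 and 6.04, all below the control arrays at 8.09, 7.93 and 7.36. It fell by 2.15 on the log2 scale (SE 0.23), to 22.5% of control (95% interval 15.9 to 31.9), with a limma adjusted p of 9.2e-05. The GATA2 cluster (TC0300012339.hg.1) was dimmer, at 5.99 ± 0.26 in control cells, 6.35 ± 0.43 in E2F2 knockdown and 5.13 ± 0.25 in GATA2 knockdown. Its GATA2 knockdown arrays read 5.42, 4.96 and 5.00, against 6.29, 5.88 and 5.80 in the control arrays. GATA2 fell by 0.87 (SE 0.23), to 54.9% of control (39.0 to 77.3), with a limma adjusted p of 0.0458. This adjustment, like the others given here for the targeted genes, was over all genes, dim ones included. Over the genes tested alone, the limma adjusted p of this fall was 0.0291. With an array left out, which also lowers power, the call was lost in 5 of 6 fits while the fall remained. It was -0.72, -0.92 and -0.96 without control replicate 1, 2 or 3 (adjusted p = 0.139, 0.0934 and 0.0742), -0.78 and -0.80 without GATA2 knockdown replicate 2 or 3 (0.159 and 0.154) and -1.01 without GATA2 knockdown replicate 1 (0.0482). After quantile normalization it was -0.87 with an adjusted p of 0.0532. E2F2 in GATA2 knockdown (log2 change 0.67, limma adjusted p = 0.135) and GATA2 in E2F2 knockdown (0.36, adjusted p = 0.442) did not pass the test.

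**Figure D1:**
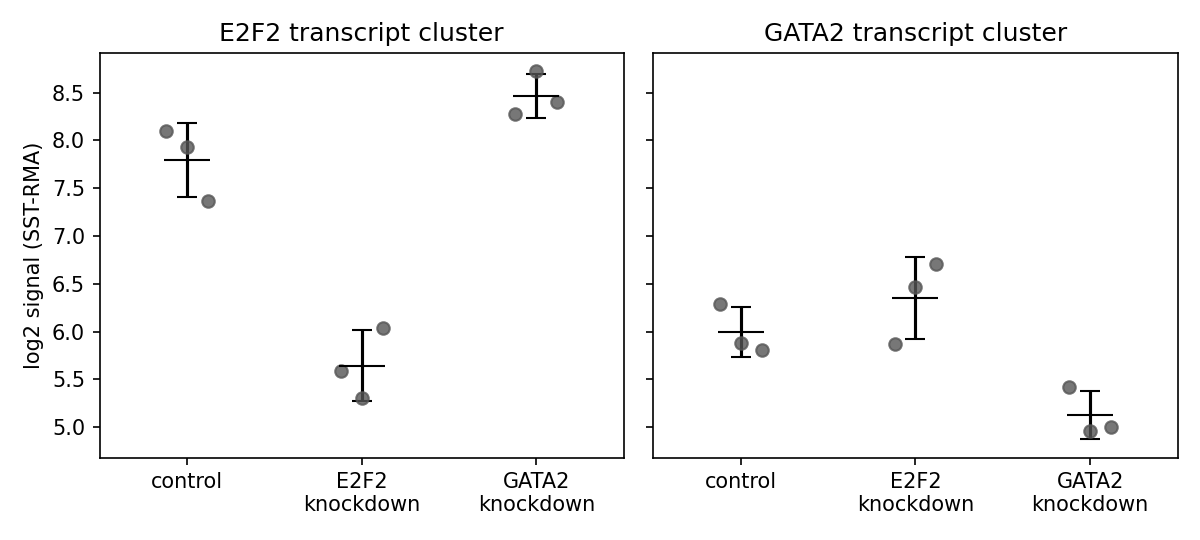
Log2 SST-RMA signal of the E2F2 and GATA2 transcript clusters in each of the 9 arrays by group (points), with the group mean (horizontal line) and SD over 3 arrays (bars). E2F2 lay at 5.64 on average in its knockdown against 7.79 in control cells, and GATA2 at 5.13 in its knockdown against 5.99.

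Of the protein-coding genes named, NT5E, the cell-surface nucleotidase that makes adenosine, fell most steeply after E2F2 knockdown. It went from 16.99 ± 0.14 to 11.62 ± 0.11 (SD, n = 3), a 41.3-fold decrease (log2 change -5.37, SE 0.14, limma adjusted p = 5.96e-10). ITGA3, an integrin subunit that binds laminin, changed by -4.32 on the log2 scale, TMEM154 by -4.25, and BHLHE40, a transcriptional repressor, by -3.94. ITGA3 lay at 4.28 in E2F2 knockdown, just below the 4.31 used as a filter, so its fall can be understated. Also among the 12 largest falls were the protease inhibitor TFPI2 (-3.89), the macrophage growth factor CSF1 (-3.70), the interstitial collagenase MMP1 (-3.48) and EMP1 (-3.30). MMP1 lay at 19.37 ± 0.10 in control cells, close to the ceiling of the scale, so its fall can be understated. The sphingomyelin synthase SGMS2 (-3.73), the endocytic GTPase DNM1 (-3.56), the ferrireductase STEAP3 (-3.25) and the glutaminyl cyclase QPCT (-3.25) completed the 12 largest falls. For SGMS2 this value came from the brighter of 2 clusters, and the other cluster changed by 0.17.

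Among the protein-coding genes named, the largest rise after E2F2 knockdown was that of TXNIP, an arrestin-like inhibitor of thioredoxin and of glucose uptake. It went from 6.43 ± 0.64 to 10.56 ± 0.20, a 17.5-fold increase (log2 change 4.13, SE 0.26, limma adjusted p = 9.49e-07). LRRC8C, a subunit of volume-regulated anion channels, rose by 3.73, the secreted factor NDNF by 3.58, the stem-cell surface protein PROM1 by 3.48 and the ketone-body enzyme BDH1 by 3.38. Further rises were found for SERPINF1 (3.07), OLFM1 (2.93), the cytokine IL1B (2.84), the matricellular protein SPARCL1 (2.80), CCDC88C (2.76) and GPM6B (2.66). KRTAP4-8 rose by 3.31, but it belongs to a family of near-identical genes that the probes can confuse. Within the E2F family, E2F1 rose by 0.97 (SE 0.21, limma adjusted p = 0.00884; 0.44 in its other cluster) and E2F3 by 1.35 (SE 0.25, adjusted p = 0.00341). Changes of E2F4, E2F5, E2F6, E2F7 and E2F8 were 0.01, -0.14, -0.13, -0.06 and -0.04 and did not pass the test. GATA1, GATA3, GATA5 and GATA6 also did not pass it (-0.07, 0.26, -0.21 and 0.06), and GATA4 lay below the filter at 3.42 in control cells.

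In all, 3081 of 22225 genes passed the limma test in E2F2 knockdown, 1916 higher and 1165 lower. Among them, 988 changed at least 2-fold, 525 up and 463 down. The excess of rises over falls depended on scaling, since quantile normalization gave 1530 higher and 1476 lower. It also varied with the array left out. Without E2F2 knockdown replicate 3 there were 1280 higher and 1123 lower, and without control replicate 3 there were 1266 higher and 955 lower. The excess was larger without control replicate 1 (1909 and 982) or E2F2 knockdown replicate 2 (1602 and 854).

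Genes of cholesterol and lipid synthesis fell as a group in E2F2 knockdown. Of 24 tested, 19 fell and 1 rose (20 and 1 when adjusted over the list alone), and the median log2 change was -1.06 (camera adjusted p = 1.07e-17, and adjusted p = 0.0273 with an estimated correlation). HMGCS1, an early enzyme of the mevalonate pathway, changed by -2.35, the sterol demethylating enzyme MSMO1 by -1.98, the cholesterol carrier STARD4 by -1.75 and the mevalonate decarboxylase MVD by -1.65. The gene that rose, named after its value was seen, was PMVK (0.75). This was the only list of the 13 with a camera call in this comparison whose call held with an estimated correlation.

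Genes of the unfolded protein and integrated stress response also fell after E2F2 knockdown. Of 42 tested, 18 fell and 0 rose (20 and 0 when adjusted over the list alone), with a median of -0.40 (camera adjusted p = 8.87e-10, but adjusted p = 0.310 with an estimated correlation). The glutathione-degrading enzyme CHAC1 changed by -2.23, the chaperone DNAJC3 by -1.43, asparagine synthetase ASNS by -1.42 and DDIT4, an inhibitor of mTOR signalling, by -1.38. In a list fixed for genes that EWSR1-FLI1 represses, 20 of 49 fell and 2 rose (27 and 3 when adjusted over the list alone), with a median of -0.50 (camera adjusted p = 5.8e-13, but adjusted p = 0.284 with an estimated correlation). Besides NT5E, the matrix crosslinking enzyme LOX (-2.64), the actin-binding protein TAGLN (-2.45) and the calcium-binding protein S100A6 (-2.29) fell most. Of 51 extracellular matrix and integrin genes, 15 fell and 5 rose (20 and 6 when adjusted over the list alone), with a median of -0.25 (camera adjusted p = 5.35e-05, but adjusted p = 0.310 with an estimated correlation). Alongside ITGA3, MMP1 and LOX, the fibronectin receptor subunit ITGA5 changed by -1.86. The matrix list and the list repressed by EWSR1-FLI1 share 14 tested genes, so their results are not independent. Fibroblast markers did not pass as a list in E2F2 knockdown (3 of 13 fell and 2 rose, or 6 and 2 when adjusted over the list alone, with a median of -0.11 and a camera adjusted p of 0.0792). This list passed as lower, however, with the mean of a gene's clusters (median -0.50, adjusted p = 0.0116), with restriction to clusters with an Entrez identifier (-0.50, 0.0238) and without E2F2 knockdown replicate 1 (-0.29, 0.0193). Of the 6 that belong to neither of these lists, PDPN (1.33) and FBLN1 (1.19) rose and 0 fell.

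Hypoxia and glycolysis genes went both ways, with 10 of 39 lower and 4 higher (11 and 4 when adjusted over the list alone) and a median of -0.13 (camera adjusted p = 0.00961, but adjusted p = 0.528 with an estimated correlation). Besides BHLHE40, the aldolase ALDOC (-2.37) and the collagen hydroxylase P4HA2 (-1.70, and -0.38 in its other cluster) fell, while hexokinase HK2 (1.96) rose. Of 41 interferon response genes, 8 fell and 2 rose (12 and 2 when adjusted over the list alone), with a median of -0.22 (camera adjusted p = 0.000723, but adjusted p = 0.310 with an estimated correlation). IFI44L (-1.55) and the antigen peptide transporter TAP1 (-0.96) were among them, the latter from 5.09 in control cells to 4.13, below the filter. Of 23 NF-kB and inflammatory genes, 6 fell and 3 rose (10 and 3 when adjusted over the list alone), with a median of -0.20 (camera adjusted p = 0.0243, but adjusted p = 0.393 with an estimated correlation). CSF1, the adhesion molecule ICAM1 (-2.0) and the cytokine IL1A (-1.88) fell, while IL1B rose.

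DNA replication genes, which include classical E2F targets, moved upward in E2F2 knockdown. Of 52 tested, 13 rose and 1 (RFC5, -0.46, named after its value was seen) fell (20 and 1 when adjusted over the list alone), with a median of 0.36 (camera adjusted p = 5.35e-05, but adjusted p = 0.528 with an estimated correlation). Cyclin CCNE2 changed by 1.40, the single-strand binding protein RPA1 by 1.26 and the polymerase subunit POLE by 0.93 (0.455 in its other cluster). Apoptosis genes had 8 members higher and 2 lower of 31 (11 and 2 when adjusted over the list alone), with a median of 0.36 (camera adjusted p = 0.00762, but adjusted p = 0.522 with an estimated correlation). The executioner caspase CASP6 (1.32) and the BH3-only protein BCL2L11 (1.29) rose, while the death receptor TNFRSF10A (-1.65) and the initiator caspase CASP8 (-1.30) fell. Of 28 p53 targets, 8 rose and 1 fell (11 and 1 when adjusted over the list alone), with a median of 0.27 (camera adjusted p = 0.0243, but adjusted p = 0.528 with an estimated correlation). The member that fell was the cell cycle inhibitor CDKN1A (-1.05), whose call was lost in 3 of 6 fits that left out an array.

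Genes that EWSR1-FLI1 activates had 13 members higher and 6 lower of 54 (15 and 6 when adjusted over the list alone), with a median of 0.21 (camera adjusted p = 0.0184, but adjusted p = 0.678 with an estimated correlation). The neuropeptide gene GRP (1.75), FEZF1 (1.27) and PPP1R1A (1.25) rose most besides E2F3. In the respiratory chain, 4 of 55 rose and 1 fell (4 and 1 when adjusted over the list alone), with a median of 0.25 (camera adjusted p = 0.00337, but adjusted p = 0.766 with an estimated correlation). The member that fell was COX4I1 (-1.16). In the siRNA machinery, 4 of 14 rose and 0 fell (6 and 0 when adjusted over the list alone), with a median of 0.29 (camera adjusted p = 0.00961, but adjusted p = 0.338 with an estimated correlation). TNRC6C (1.08) and AGO2 (0.85), parts of the silencing complex, were among them. Without E2F2 knockdown replicate 3 the camera adjusted p rose to 0.0552 for the EWSR1-FLI1 activated list, 0.0604 for p53 targets and 0.0546 for NF-kB and inflammatory genes, and for the last it was 0.0523 without control replicate 3. The 75th percentile filter ended the calls of the EWSR1-FLI1 activated list (median 0.28, camera adjusted p = 0.0864), p53 targets (0.24, 0.185) and the siRNA machinery (0.29, 0.0548). Restriction to clusters with an Entrez identifier ended that of p53 targets (0.0929). By fry, which asks a different question, hypoxia and glycolysis (0.0834) and the respiratory chain (0.160) did not pass. Medians of lists with a call also moved by over 1.5 times. That of NF-kB and inflammatory genes was -0.08 without control replicate 1, -0.31 without E2F2 knockdown replicate 3 and -0.54 with the 75th percentile filter, and that of hypoxia and glycolysis was -0.06 without control replicate 1 or E2F2 knockdown replicate 1 and -0.20 without E2F2 knockdown replicate 3. The median of interferon genes was -0.14 without E2F2 knockdown replicate 2, that of the respiratory chain 0.16 without E2F2 knockdown replicate 3 and with quantile normalization, and that of p53 targets 0.18 with quantile normalization.

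The other 12 lists did not pass camera in E2F2 knockdown, with adjusted p from 0.0792 to 0.942. In the E2F and RB family, 5 of 29 rose and 3 fell (6 and 3 when adjusted over the list alone), the cell cycle kinase CDK6 (1.13) being among those that rose. The targeted gene E2F2 is itself in this list and is counted among the 3 that fell. Mitosis genes had 2 of 59 higher, BIRC5 (0.71) and CENPN (0.61), and 0 of either direction when adjusted over the list alone, and both calls were lost in some fits that left out an array. Of 35 MYC and ribosome biogenesis genes, 5 rose (5 when adjusted over the list alone), MYC itself by 0.75. Neural genes split into 10 higher and 8 lower of 40 (12 and 9 when adjusted over the list alone), with the neuronal filament INA at 2.42, the adhesion molecule NCAM1 at 1.74 (0.66 in its other cluster), the growth cone protein GAP43 at -2.39 and the filament NEFL at -2.18. Autophagy and lysosome genes had 10 higher and 4 lower of 36 (10 and 4 when adjusted over the list alone), such as the cathepsin CTSK (1.60) and LAMP2 (-1.52). Immediate early and AP-1 genes had 7 higher and 7 lower of 34 (9 and 10 when adjusted over the list alone), with the signalling inhibitor SPRY1 at 2.08 and FOSL1 at -1.64. GATA-linked hematopoietic and endothelial genes had 6 higher and 0 lower of 33 (6 and 1 when adjusted over the list alone), among them EMCN (1.44) and KITLG (1.41). Histones (48 tested), ribosomal proteins (47), epithelial markers (7) and hematopoietic markers (11) had 0 members that changed, also when adjusted over the list alone. Their medians were 0.17, 0.14, -0.09 and 0.01. For immediate early, neural and hematopoietic marker genes the median was above 0 while camera pointed down. Histones passed as higher without control replicate 1 (median 0.30, adjusted p = 0.00188), without E2F2 knockdown replicate 1 (0.23, 0.0158) and with no filter on dim clusters (0.17, 0.0112). Autophagy and lysosome genes passed with no filter (adjusted p = 0.0346), ribosomal proteins without E2F2 knockdown replicate 1 (0.0472) and epithelial markers with fry (0.0281).

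**Figure D2:**
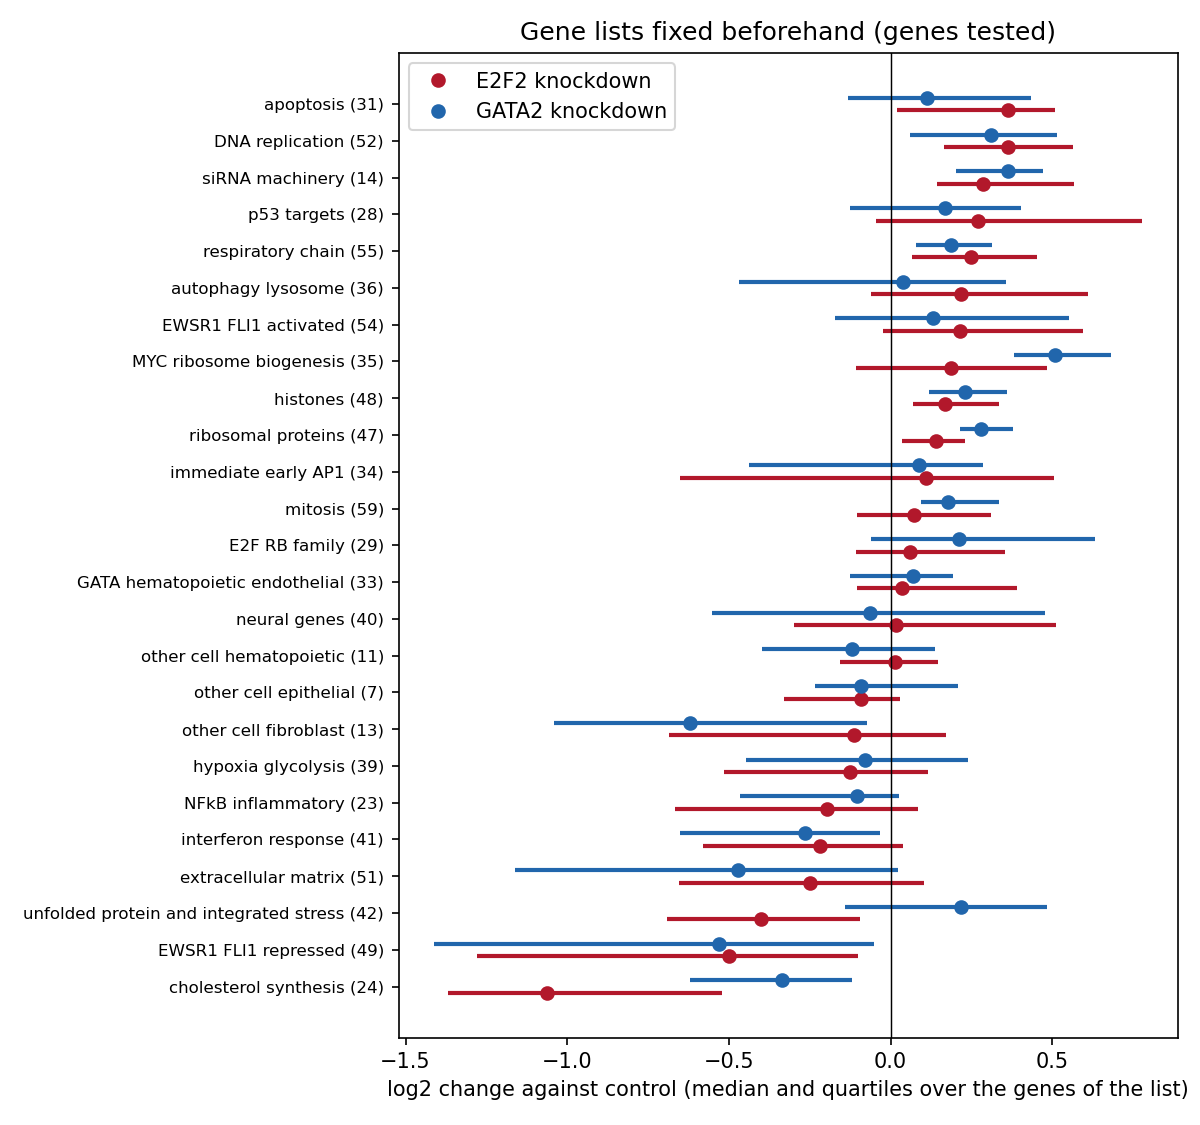
Median log2 change against control of each of the 25 gene lists (points) with the quartiles over its genes (lines), in E2F2 knockdown (red) and GATA2 knockdown (blue), with the number of genes tested in parentheses. Cholesterol synthesis lay lowest in E2F2 knockdown (-1.06), and the unfolded protein and integrated stress list lay at -0.40 in E2F2 knockdown and 0.22 in GATA2 knockdown.

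After GATA2 knockdown, NT5E fell from 16.99 ± 0.14 to 12.84 ± 0.08 (SD, n = 3), a 17.8-fold decrease (log2 change -4.15, SE 0.14, limma adjusted p = 2.68e-08). ITGA3 changed by -3.66 on the log2 scale, the matrix proteoglycan BGN by -3.50, the angiogenic growth factor PGF by -3.24 and the vesicle protein SYT11 by -3.23. The endothelial diaphragm protein PLVAP (-3.10), the axon guidance factor DRAXIN (-3.06), the mitochondrial serine carrier SFXN3 (-2.93), TAGLN (-2.84), EMP1 (-2.84), FHDC1 (-2.83) and the gelatinase MMP2 (-2.81) completed the 12 largest falls. The largest rise among the protein-coding genes named was that of SCNN1G, a subunit of the epithelial sodium channel. It went from 5.68 ± 0.38 to 10.71 ± 0.12, a 32.6-fold increase (log2 change 5.03, SE 0.23, limma adjusted p = 2.03e-07). It was followed by OLFM1 (2.62), the granzyme inhibitor SERPINB9 (2.61), CAPN6 (2.60), INA (2.46), the nucleosome-binding protein HMGN5 (2.25), HK2 (2.20), the cationic amino acid transporter SLC7A2 (2.20), the peptide hormone UTS2 (2.18), TXNIP (2.15) and the transcription factor MYB (2.14). The mitochondrial creatine kinase CKMT1A rose by 2.17, but the probes can confuse it with its near-identical copy. For MYB the other cluster of the gene changed by -0.10.

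Within the E2F family, E2F5 rose by 0.66 and E2F6 by 0.92 after GATA2 knockdown (limma adjusted p = 0.0101 and 0.00326, the call of E2F5 being lost in 1 of 6 fits that left out an array), while E2F1, E2F3, E2F7 and E2F8 did not pass the test (0.54, 0.67, 0.00 and 0.31). E2F4 passed with a change of 0.87 (adjusted p = 0.032), but its call was lost in 4 of 6 fits that left out an array. GATA1, GATA3, GATA5 and GATA6 did not pass (-0.06, 0.25, 0.07 and 0.07). In all, 2314 genes passed in GATA2 knockdown, 1399 higher and 915 lower, of which 692 changed at least 2-fold (316 up and 376 down). Quantile normalization gave 1116 higher and 1120 lower. The count fell to 1493 without control replicate 2 (812 higher), 1485 without control replicate 3 (765 higher), 1458 without GATA2 knockdown replicate 2 (754 higher) and 1378 without GATA2 knockdown replicate 3 (701 higher).

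Of the 49 genes in the list repressed by EWSR1-FLI1, 24 fell in GATA2 knockdown and 1 rose (27 and 3 when adjusted over the list alone), with a median of -0.53 (camera adjusted p = 7.34e-17, but adjusted p = 0.0838 with an estimated correlation). NT5E, BGN, TAGLN and the TGF-beta receptor TGFBR2 (-2.69) fell most. Of 51 extracellular matrix and integrin genes, 23 fell and 3 rose (27 and 4 when adjusted over the list alone), with a median of -0.47 (camera adjusted p = 6.42e-15, but adjusted p = 0.0838 with an estimated correlation), while the protease ADAMTS1 rose by 2.11. Fibroblast markers fell too, with 7 of 13 lower and 0 higher (7 and 0 when adjusted over the list alone) and a median of -0.62 (camera adjusted p = 3.94e-07, but adjusted p = 0.0838 with an estimated correlation). ACTA2 (-1.66), COL1A2 (-1.29) and PDGFRB (-1.04) were among them. Of these 13 markers, 7 belong to the matrix list or the list repressed by EWSR1-FLI1, and of the other 6, 3 fell and 0 rose. The matrix list and the list repressed by EWSR1-FLI1 also share 14 tested genes, so the calls of these lists are not independent. Of 41 interferon response genes, 9 fell and 0 rose (13 and 0 when adjusted over the list alone), with a median of -0.26 (camera adjusted p = 3.62e-07, but adjusted p = 0.0838 with an estimated correlation). DTX3L (-1.78), PARP14 (-1.50) and HLA-B (-1.07) fell most.

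Cholesterol and lipid synthesis genes also fell in GATA2 knockdown, with 8 of 24 lower and 0 higher (11 and 0 when adjusted over the list alone) and a median of -0.34 (camera adjusted p = 1.16e-07, but adjusted p = 0.0838 with an estimated correlation). STARD4 (-1.01), the fatty acid elongase ELOVL6 (-0.90) and the sterol reductase TM7SF2 (-0.89) were among them. Of 23 NF-kB and inflammatory genes, 3 fell and 0 rose (3 and 0 when adjusted over the list alone), with a median of -0.10 (camera adjusted p = 0.00157, but adjusted p = 0.172 with an estimated correlation). These were CSF1 (-2.18), ICAM1 (-1.62) and IL1A (-0.92), the last of which lost its call in 4 of 6 fits that left out an array. Hypoxia and glycolysis genes had 8 of 39 lower and 3 higher (8 and 4 when adjusted over the list alone), with a median of -0.08 (camera adjusted p = 0.0319, but adjusted p = 0.665 with an estimated correlation). BHLHE40 (-1.71) and ALDOC (-1.50) fell and HK2 rose.

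Genes of MYC and ribosome biogenesis rose in GATA2 knockdown, with 14 of 35 higher and 0 lower (26 and 0 when adjusted over the list alone) and a median of 0.51 (camera adjusted p = 2.01e-10, but adjusted p = 0.442 with an estimated correlation). IMP4 changed by 1.23, MYC by 1.11, RCL1 by 1.03 and LYAR by 1.01. DNA replication genes had 10 of 52 higher and 0 lower (11 and 0 when adjusted over the list alone), with a median of 0.31 (camera adjusted p = 8.05e-05, but adjusted p = 0.665 with an estimated correlation). The ribonucleotide reductase subunit RRM2 (1.18), RPA1 (1.13), POLA1 (0.93) and CDC45 (0.84) were among them. Unfolded protein and integrated stress genes had 8 of 42 higher and 2 lower (16 and 5 when adjusted over the list alone), with a median of 0.22 (camera adjusted p = 0.0441, but adjusted p = 0.692 with an estimated correlation). The members that rose most were the serine synthesis enzyme PSAT1 (1.45), the cystine transporter SLC7A11 (1.12), the seryl-tRNA synthetase SARS1 (1.04) and the cysteine-producing enzyme CTH (1.02).

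A further 5 lists shifted upward with few members passing on their own. Mitosis genes had 4 of 59 higher (4 when adjusted over the list alone), among them CDC20 (0.88) and NCAPD2 (0.72), with a median of 0.18 (camera adjusted p = 0.00465, but adjusted p = 0.665 with an estimated correlation). Ribosomal proteins had 1 of 47 higher, RPL19 (0.68), and 0 when adjusted over the list alone, with a median of 0.28 (camera adjusted p = 2.14e-05, but adjusted p = 0.665 with an estimated correlation). Histones had 1 of 48 higher, H1-1 (0.68), and 0 when adjusted over the list alone, with a median of 0.23 (camera adjusted p = 0.00606, but adjusted p = 0.785 with an estimated correlation). The respiratory chain had 2 of 55 higher, NDUFB4 (0.71) and NDUFA9 (0.64), and 0 when adjusted over the list alone, with a median of 0.19 (camera adjusted p = 0.0194, but adjusted p = 0.785 with an estimated correlation). The siRNA machinery had 2 of 14 higher, TARBP2 (0.71) and XPO5 (0.63), and 1 lower, AGO4 (-0.67) (7 and 1 when adjusted over the list alone), with a median of 0.36 (camera adjusted p = 0.0441, but adjusted p = 0.490 with an estimated correlation). Each of the genes named here except NCAPD2 lost its call in at least 3 of 6 fits that left out an array.

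Several of the 15 camera calls in GATA2 knockdown ended when an array was left out. Without control replicate 1 the adjusted p was 0.0795 for hypoxia and glycolysis, 0.0991 for the siRNA machinery and 0.128 for unfolded protein and integrated stress, and for the last it was 0.0547 without control replicate 2. Without control replicate 3 it was 0.210 for histones and 0.195 for the respiratory chain, with medians down to 0.10 in both. Without GATA2 knockdown replicate 2 the calls of these 5 lists and of mitosis ended, with adjusted p of 0.0773, 0.154, 0.148, 0.189, 0.379 and 0.148 in the order hypoxia, siRNA machinery, unfolded protein, histones, respiratory chain and mitosis, and 9 lists passed in all. In that fit the medians of histones (0.12) and the respiratory chain (0.11) had also fallen by over 1.5 times, while for the siRNA machinery (0.36), unfolded protein (0.21) and mitosis (0.14) they moved by less. Quantile normalization ended the calls of mitosis (median 0.12, adjusted p = 0.0940), the respiratory chain (0.09, 0.115), the siRNA machinery (0.106) and unfolded protein and integrated stress (0.106). The 75th percentile filter ended those of histones (median 0.23, adjusted p = 0.0618), mitosis (0.18, 0.0531) and the respiratory chain (0.19, 0.128). It also ended those of the siRNA machinery (0.35, 0.193) and unfolded protein (0.22, 0.193). Array weights ended those of hypoxia, the siRNA machinery and unfolded protein (0.0553 each), and the mean of a gene's clusters that of the siRNA machinery (0.0659). Restriction to clusters with an Entrez identifier ended those of the siRNA machinery (0.103) and unfolded protein (0.0699). By fry, a test against no change, histones (0.285), hypoxia (0.306), mitosis (0.0670), the respiratory chain (0.270) and ribosomal proteins (0.0924) did not pass. Where calls held, the median of hypoxia and glycolysis was -0.14 without control replicate 3, -0.15 without GATA2 knockdown replicate 3, -0.16 with quantile normalization and -0.13 with arrays centred on their median, and -0.13 in the fit without GATA2 knockdown replicate 2 that ended its call. The median of NF-kB genes was -0.20 without control replicate 2, -0.16 with median centring and -0.06 with array weights, that of fibroblast markers -0.35 with no filter on dim clusters and -0.95 with the 75th percentile filter, and that of histones 0.15 with quantile normalization.

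The other 10 lists did not pass camera in GATA2 knockdown, with adjusted p from 0.0665 to 0.855. In the E2F and RB family, 7 of 29 rose and 2 fell (8 and 2 when adjusted over the list alone), with cyclin CCND2 at 1.80 and MYBL1 at -1.29. Genes that EWSR1-FLI1 activates had 13 of 54 higher and 6 lower (16 and 8 when adjusted over the list alone), with the receptor KIT at 1.92, GSTM4 at 1.83 and the neuropeptide receptor NPY5R at -1.48. GATA-linked genes had 4 of 33 higher and 3 lower (4 and 3 when adjusted over the list alone), with MYB, KIT and KITLG (1.19) higher and IKZF1 (-1.43) lower. The targeted gene GATA2 is itself in this list and is counted among the 3 that were lower. Neural genes had 8 of 40 higher and 8 lower (10 and 12 when adjusted over the list alone), such as INA, SYT11 and GAP43 (-2.60). Immediate early and AP-1 genes had 5 of 34 higher and 7 lower (6 and 7 when adjusted over the list alone), with JUND at 1.60 and EGR1 at 1.20. Autophagy and lysosome genes had 1 of 36 higher and 5 lower (2 and 6 when adjusted over the list alone), with the lysosomal lipase LIPA at -1.34 (its other clusters changed by -0.19 and -0.14). For the last 2 lists the median was above 0 while camera pointed down. Apoptosis genes had 3 of 31 higher (5 higher and 3 lower when adjusted over the list alone), of which the caspase inhibitor XIAP changed by 0.85. Of 28 p53 targets, 2 rose and 1 fell (2 and 1 when adjusted over the list alone). Epithelial markers had 1 of 7 higher, MUC1 (0.67), and hematopoietic markers had 1 of 11 higher, HBA1 (0.73), and 1 lower, CD79B (-0.56), with the same counts when adjusted over the list alone. These 3 markers lost their calls in at least 5 of 6 fits that left out an array. The E2F and RB family passed as higher with no filter on dim clusters (median 0.19, adjusted p = 0.0209), with the intensity trend and robust prior (0.21, 0.0415) and without GATA2 knockdown replicate 1 (0.31, 0.0333), and neural genes passed as lower without GATA2 knockdown replicate 3 (adjusted p = 0.0455).

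A direct test of the knockdowns against each other, in which the level of the control arrays cancels out, asked which changes differed between them. IL1B was 9.91-fold higher in E2F2 knockdown than in GATA2 knockdown (log2 difference 3.31, SE 0.16, limma adjusted p = 5.76e-07). BGN was 3.30 higher on the log2 scale, SPARCL1 3.19, the netrin receptor UNC5C 3.09 and KRTAP4-8 3.37, the last with the limit on near-identical genes named above. TFPI2 differed by -3.17, SCNN1G by -3.07, MARCHF4 by -2.84, E2F2 by -2.82 and the mitochondrial peroxidase PRDX3 by -2.79, all lower in E2F2 knockdown. In all, 2261 genes differed, 1193 higher and 1068 lower in E2F2 knockdown, and 772 of them at least 2-fold. The balance of directions turned with quantile normalization (1192 higher and 1225 lower), with array weights (1309 and 1447), without E2F2 knockdown replicate 3 (932 and 1145) and without GATA2 knockdown replicate 1 (861 and 877). It leaned further toward higher without E2F2 knockdown replicate 1 (897 and 680) or 2 (994 and 681) and without GATA2 knockdown replicate 2 (940 and 689) or 3 (901 and 676).

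In the unfolded protein and integrated stress list, 22 of 42 were lower and 0 higher in E2F2 knockdown (27 and 1 when adjusted over the list alone), with a median of -0.65 (camera adjusted p = 1.49e-14, but adjusted p = 0.302 with an estimated correlation). CHAC1 (-2.62), ASNS (-2.37) and SLC7A11 (-1.99) were among them. Cholesterol and lipid synthesis had 16 of 24 lower and 1 higher (17 and 1 when adjusted over the list alone), with a median of -0.63 (camera adjusted p = 2e-09, but adjusted p = 0.143 with an estimated correlation), HMGCS1 at -1.53 among them. MYC and ribosome biogenesis had 8 of 35 lower and 0 higher (14 and 1 when adjusted over the list alone), with a median of -0.38 (camera adjusted p = 7.7e-07, but adjusted p = 0.929 with an estimated correlation). Ribosomal proteins had 0 of 47 members that differed, also when adjusted over the list alone, and a median of -0.14 (camera adjusted p = 0.00821, but adjusted p = 0.929 with an estimated correlation).

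Lists higher in E2F2 knockdown than in GATA2 knockdown were the extracellular matrix, with 14 of 51 higher and 6 lower (17 and 9 when adjusted over the list alone, median 0.22, camera adjusted p = 0.0263, but adjusted p = 0.929 with an estimated correlation), and fibroblast markers, with 4 of 13 higher and 1 lower (5 and 1 when adjusted over the list alone, median 0.39, camera adjusted p = 0.00322, but adjusted p = 0.593 with an estimated correlation). BGN, MMP2 (2.14) and MMP14 (2.13) led the matrix genes, while MMP1 (-2.46) was lower. Autophagy and lysosome genes had 7 of 36 higher and 1 lower (11 and 2 when adjusted over the list alone, median 0.29, camera adjusted p = 0.00821, but adjusted p = 0.929 with an estimated correlation), with MAP1LC3B at 1.26 (0.19 in its other cluster). The call of the matrix list ended without E2F2 knockdown replicate 1 (median 0.08, adjusted p = 0.0508) or 3 (0.15, 0.0672), that of ribosomal proteins without E2F2 knockdown replicate 1 (0.105) or GATA2 knockdown replicate 2 (0.193), and that of autophagy without E2F2 knockdown replicate 3 (0.0674). The mean of a gene's clusters (median 0.05, adjusted p = 0.0631) and restriction to clusters with an Entrez identifier (0.15, 0.118) ended the call of the matrix list. Tested against no change by fry, autophagy (0.189), MYC and ribosome biogenesis (0.0634) and ribosomal proteins (0.330) did not pass. The median of the matrix list was 0.33 with the 75th percentile filter and 0.14 without GATA2 knockdown replicate 3, that of fibroblast markers 0.23 without E2F2 knockdown replicate 1, that of autophagy 0.19 without GATA2 knockdown replicate 1, and that of ribosomal proteins -0.23 and -0.09 without GATA2 knockdown replicate 1 or 2. The other 18 lists did not pass camera, with adjusted p from 0.0656 to 0.957 and medians from -0.17 to 0.22, DNA replication at 0.03 among them. Of these, mitosis passed as lower in E2F2 knockdown with the intensity trend and robust prior (0.0471) and without GATA2 knockdown replicate 1 (0.0191), apoptosis as higher with no filter on dim clusters (0.0431) and without GATA2 knockdown replicate 2 (0.0479), and the respiratory chain as higher without GATA2 knockdown replicate 2 (0.0350). In this comparison the median lay below 0 but the mean above 0 for genes repressed by EWSR1-FLI1 (-0.05 and 0.06), NF-kB genes (-0.07 and 0.05) and the siRNA machinery (-0.02 and 0.11), and camera pointed up for hematopoietic markers despite a median of -0.15.

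**Figure D3:**
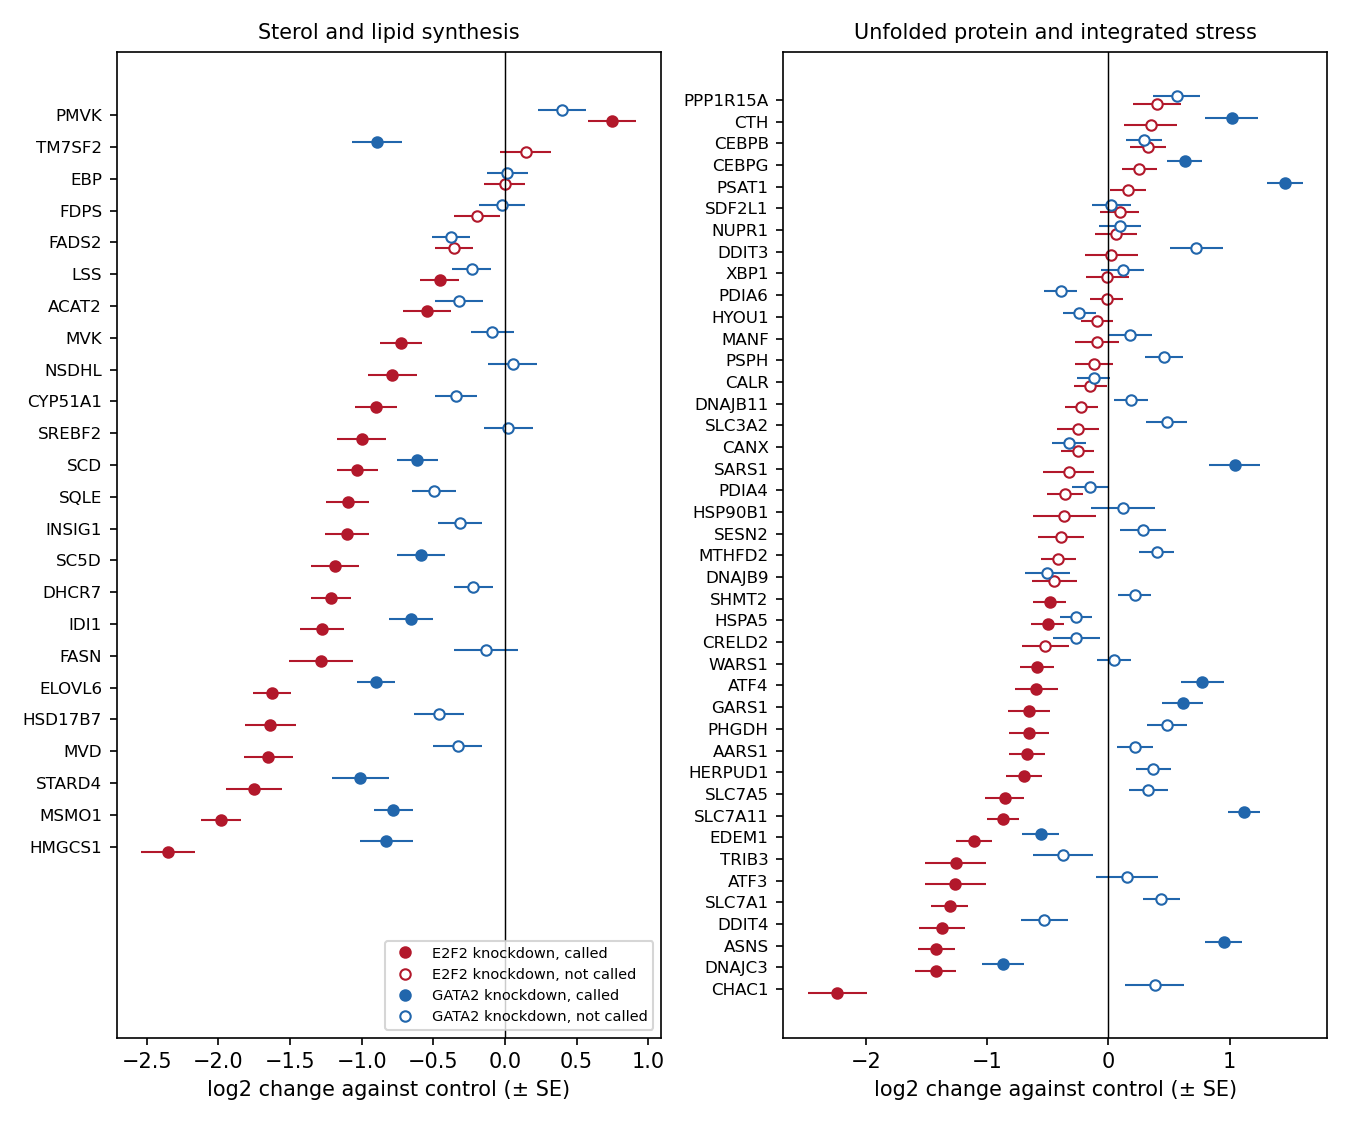
Log2 change against control with its SE for each tested gene of the cholesterol and lipid synthesis list (left) and of the unfolded protein and integrated stress list (right), in E2F2 knockdown (red) and GATA2 knockdown (blue), filled where the limma adjusted p was under 0.05. In E2F2 knockdown 19 of 24 sterol and lipid genes and 18 of 42 stress genes fell, and in GATA2 knockdown 8 of 24 fell and 8 of 42 rose.

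Many genes changed in the same direction in both knockdowns. NT5E and ITGA3 were among the steepest falls of each, PLVAP changed by -2.92 in E2F2 knockdown and -3.10 in GATA2 knockdown, and EMP1 by -3.30 and -2.84. OLFM1 rose by 2.93 and 2.62, INA by 2.42 and 2.46, TXNIP by 4.13 and 2.15, and APELA, a peptide ligand of the apelin receptor, by 2.00 and 2.05. In all, 1091 genes passed the limma test in both with the same sign, 659 higher and 432 lower, and 69 passed with opposite signs. Independent lists of these sizes would share 120.6 higher and 48.0 lower genes. In 100 simulations of unchanged groups, with simulated controls that both knockdowns shared, the median was 0 shared genes. That median sets no level for genes that do respond. Across genes, which are not independent replicates, the log2 changes correlated at r = 0.55 (rho = 0.52), where the simulations gave a median r of 0.499. Their covariance was 0.111 against 0.0225 in the simulations, a difference of 0.088, and 69.4% of genes had the same sign against 66.7%. The simulations drew each gene independently, whereas genes can vary together between real arrays. With 3 control arrays the controls were not split, since 1 knockdown would have kept fewer than 2 of them, and part of the excess may come from sharing them. The shared count fell to 723 without control replicate 2, 715 without control replicate 3 and 724 without GATA2 knockdown replicate 3.

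**Figure D4:**
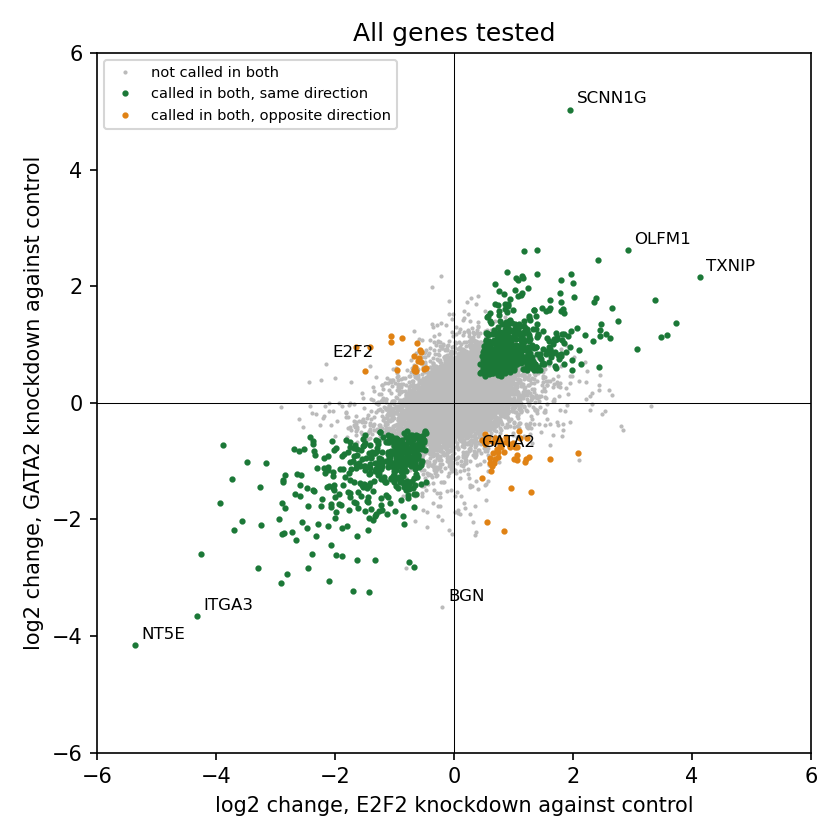
Log2 change against control of the 22225 genes tested, E2F2 knockdown on the horizontal and GATA2 knockdown on the vertical axis, with 1091 genes that passed in both in the same direction in green and 69 in opposite directions in orange. NT5E (-5.37 and -4.15) lies farthest toward the lower left, and SCNN1G lies at 1.96 and 5.03.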

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

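All results in this part come from transcript clusters that the comparisons of genes left out, and none was tested for a technical origin. Among 44097 clusters without a single gene symbol that passed the same brightness filter, limma called 124 higher and 84 lower in E2F2 knockdown than in control cells. They are named here because they are signal in data that lie outside the comparisons. The largest rise was that of cluster TC0700013538.hg.1, by 6.02 on the log2 scale, which exceeds the largest rise of any protein-coding gene named for E2F2 knockdown (TXNIP, 4.13). In GATA2 knockdown 20 such clusters were higher and 26 lower, with a largest rise of 2.14 for TC1900008564.hg.1. Groups of 3 arrays were not tested for outlying samples.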

How the results depend on the processing

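Restriction to clusters with an Entrez identifier was chosen after seeing the data; it moved no count of genes or lists by 1.5 times. No result reversed its direction past the threshold under any alternative (sign changes between values that both missed the threshold were not counted). With a minimum absolute log2 change of 1 the counts were 988 (E2F2 knockdown), 692 (GATA2 knockdown), 772 (direct) and 276 (shared), by construction. Over all clusters of the file they were 1651, 815 and 1098, where dim and unnamed clusters enter the adjustment. With an estimated correlation 1, 0 and 0 lists passed, and fry called 4 in the direct comparison. In GATA2 knockdown, where the estimated correlation left 0 lists, fry called 10. GATA2 in its own knockdown missed the threshold under quantile normalization (-0.87, adjusted p = 0.0532) and under the replicate block (-0.87, adjusted p = 0.0848); the cause was not tested. Leaving out each array in turn, counts ran from 2217 to 2891 (E2F2), 1378 to 2211 (GATA2), 1577 to 2077 (direct) and 715 to 1078 (shared), lists from 10 to 16, 9 to 16 and 5 to 8, E2F2 in its knockdown from -2.37 to -1.98, and GATA2 in its knockdown from -1.01 to -0.72, with adjusted p from 0.0482 to 0.159 and the call lost in 5 of 6 fits. Fewer arrays lower the counts by construction. Same-numbered replicates did not deviate together (r from -0.12 to 0.15), so the numbers were not taken as pairs. With the replicate number as a block, 2720, 1918 and 2037 genes passed, and in GATA2 knockdown the camera calls of the siRNA machinery (adjusted p = 0.0521) and of unfolded protein and integrated stress (0.0581) ended. Counting each named gene once per fit, calls were lost 201 times when an array was left out and 82 times under other alternatives, and gained 6 and 23 times. Counting lists likewise, calls were lost 21 and 67 times and gained 9 and 9 times. Misses by fry, a test against no change, were counted as losses here. Signal over background limits dim genes, such as GATA2 at 5.99 in control cells.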

Other observations

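The tests of whether a knockdown lowered the other target, of the estimated correlation of the DNA replication list and of a rise of another E2F were chosen only after the result was seen.

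Of the 69 genes that passed in both knockdowns with opposite signs, some are named here that were chosen after their values were seen. SPRY1, an inhibitor of growth factor signalling, changed by 2.08 in E2F2 knockdown and -0.87 in GATA2 knockdown, and the direct limma test gave a difference of 2.95 (adjusted p = 3.65e-06). The matrix protein FBLN1 changed by 1.19 and -1.01, the receptor kinase MERTK by 1.21 and -0.96, the neuronal kinase DCLK1 by 1.61 and -0.97, and asparagine synthetase ASNS by -1.42 and 0.95. Isolated steep falls in E2F2 knockdown, also chosen after their values were seen, were those of PRDX3 (-2.43 against 0.36 in GATA2 knockdown) and of the mitochondrial channel VDAC1 (-2.38 against -0.18). GNPDA1 changed by -1.65 in E2F2 knockdown and 0.95 in GATA2 knockdown. The sequences of the siRNA pools were not used here, so off-target effects on these genes or any others were not tested.

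For genes that changed the same way in both knockdowns, shared control arrays alone predict a covariance of the log2 changes near that of unchanged groups. The covariance was 0.111 against at most 0.0238 in 100 simulations. The simulations drew each gene independently, whereas genes can vary together between real arrays. They therefore cannot set aside a joint deviation of the shared control arrays. If a knockdown lowered the other's target, GATA2 would fall in E2F2 knockdown by at least 0.5 times its fall in its own (-0.87), but the lower 95% limit of its change was -0.138, and that of E2F2 in GATA2 knockdown was 0.17. Of the shared genes 20.6% passed the direct test and 866 did not, against 10.2% of all genes tested. Passing it was planned as evidence against a shift of the control arrays, but it is none, since a gene shifted in the controls can also differ through 1 knockdown. A shift of the controls and a common response to knockdown cannot be told apart for either part, because both comparisons against control use the same control arrays, and their level cancels out of the direct comparison.

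The upward shift of DNA replication genes in E2F2 knockdown did not rest on E2F2 knockdown replicate 3, without which the median was 0.303. It does not stand out from arrays whose genes vary together, since camera with an estimated correlation gave an adjusted p of 0.528. A candidate explanation is a rise of another activating E2F, and E2F3 rose by 1.35 (E2F1 by 0.97, and by 0.44 in its other cluster). No test linked the rise of E2F3 to the list. The list also shifted upward in GATA2 knockdown (median 0.31), where E2F3 and E2F1 changed by 0.67 and 0.54 and did not pass the limma test. In the direct comparison its median was 0.03 (camera adjusted p = 0.530), so the shift was not particular to E2F2 knockdown.

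In E2F2 knockdown the fall of sterol synthesis genes held when the deposited values were rescaled. The median was -1.12 at its nearest to 0 under quantile normalization or median centring. These values had already been normalized by SST-RMA, which such a check cannot test, and it covered E2F2 knockdown only. A lower transcript level of SREBF2, an activator of sterol synthesis genes, may contribute in E2F2 knockdown, where SREBF2 changed by -1.0 on the log2 scale. No test linked this fall to the list, so cause and consequence were not told apart. In GATA2 knockdown SREBF2 changed by 0.02, with a lower 95% limit of -0.35. A fall of 0.5 times the median of the list (-0.17) lies within that limit, so the test leaves a lower SREBF2 level open there.

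Other splits of the arrays were compared with the real groups. Of the 10 splits of 6 arrays into 3 and 3, only 1, the real split, gave as many genes as the 3081, 2314 and 2261 found, and the highest other count was 0 in each case, but 10 splits are too few for a share under 0.05. For gene lists, as many passed in 2 of 10 splits in E2F2 knockdown (13 against a highest other of 13), 1 of 10 in GATA2 knockdown (15 against 14) and 3 of 10 in the direct comparison (7 against 8), again with too few splits. The camera calls at the preset correlation thus also arose in mixed splits. Each part of a mixed split holds unequal numbers of arrays from the 2 groups, so part of any real difference remains. The counts of lists in mixed splits therefore set no chance level. For the shared genes, 1 of 100 regroupings of the 9 arrays, the real grouping, gave as many as 1091, the highest other being 626. A lower count is likely in mixed groups, whose spread is wider when the real groups differ. The regroupings thus address only whether the groups differ at all. They cannot exclude a shift of the 3 shared control arrays or a difference between cultures.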
